A study of Homo sapiens with 12 samples.

How the data were processed

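The labels describe A549 cells that stably carried a control or an FXR short hairpin RNA, sham irradiated or irradiated with ionizing radiation, in 4 groups of 3 libraries each that the design text calls biological replicates. Per the labels' protocols, messenger RNA was selected with poly-T beads and copied into cDNA with random hexamers. Per the submitters' processing notes, reads were aligned to hg38 and DESeq2 1.20.0 was used, without a stated step. The aligner, the counting tool, the strand setting and the radiation dose are not given in the sources used here. The deposited table holds a raw count for each gene and library. All 58735 gene identifiers and their coordinates equal those of GENCODE 29 (Ensembl 94), and 58207 were paired with a current gene symbol. FXR was taken as NR1H4, the farnesoid X receptor, which the labels do not spell out, and FXR1, FXR2 and FMR1 were looked at beside it.

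Of the genes, 33302 had a count in any library and 16053, of which 13299 code for proteins, were kept by filterByExpr in edgeR (minimum count 10, minimum total count 15). Counts were scaled by TMM and fitted with edgeR's quasi-likelihood model with 1 coefficient per group over all 12 libraries, which left 8 residual degrees of freedom (common biological coefficient of variation 0.0874, prior degrees of freedom 11.9). The tests were radiation within each line, knockdown within each treatment, and the difference between the radiation responses. Benjamini-Hochberg adjusted p under 0.05 was called, and standard errors are the log2 fold change divided by the square root of F. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

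The comparisons, the 32 gene lists, the genes always given and the alternatives below were chosen before the data were examined. Lists were tested with camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 30 lists with at least 5 measured members in each comparison. Camera with a correlation estimated from the data and the rotation test fry were run beside it. The lists cover p53 targets, apoptosis regulators, G2/M and mitosis, DNA replication and S phase, replication-dependent histones, homologous recombination and Fanconi genes, interferon-stimulated genes, inflammatory cytokines and chemokines, secreted factors of senescent cells, antigen presentation, immune checkpoint and NK ligands, FXR targets and bile acid genes, cholesterol and fatty acid synthesis, NRF2 targets, ATF4 and unfolded protein response, ferroptosis, mesenchymal and matrix, epithelial junction and keratin, lung alveolar and airway genes, YAP/TEAD targets, hypoxia and glycolysis, respiratory chain, mitochondrially encoded mRNAs, ribosomal proteins, lysosome and autophagy, immediate early and heat shock genes, and markers of fibroblasts, leukocytes, endothelial cells, hepatocytes and erythroid cells.

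Genes named are 16 always given (NR0B2 among them was not tested), the protein-coding genes of at least 5 CPM with the largest changes (8 each way, 4 each way for radiation in shFXR cells) whose groups did not overlap, a condition not set for the difference of responses, and up to 3 called members of each list with the smallest adjusted p and 1 in the other direction. Some genes that this rule selects are not reported here. The size of the response was measured over genes with a called radiation effect averaged over the lines.

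Alternatives were RLE scaling, total counts only, no filter, a filter at a mean of 5 CPM, protein-coding genes only, the replicate number as a block, only the groups compared, DESeq2's Wald test, and leaving out each library in turn. Leaving out mitochondrial genes and limma with voom sample weights were added after seeing the data. In each of 5 simulations with 15744 genes, 100 genes were changed 1.5-fold and 100 others 2-fold. The fit recovered 59.3% of 1.5-fold and 81.1% of 2-fold changes for radiation in shControl cells, with 6.14% false calls. It recovered 34.4% and 68.4% for the difference of responses, with 6.84% false calls. In comparisons without simulated changes at most 1 gene was called. A G2/M list lowered 1.5-fold was called in all 5 simulations, and 1 call of another list was made. Genes were simulated independently of each other, so these simulations cannot check list calls on correlated genes. Each gene was also given the same spread in every group, whereas the shControl replicates varied more than the shFXR replicates. The shares recovered and the false calls may therefore not hold for comparisons that use the shControl libraries.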

Results

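Gene expression was measured by RNA sequencing in A549 cells, an established human lung cancer line, that stably carried a control short hairpin RNA (shControl) or one against FXR (shFXR). Cells of each line were sham irradiated or taken 3 days after ionizing radiation, which gave 4 groups of 3 biological replicates. The time at which sham cells were taken is not given in the sources used here, so a difference in time in culture would enter the comparisons with irradiated cells. Library totals ranged from 17.1 to 19.0 M counts, and 16053 of 58735 genes had enough counts to be tested. The first principal component held 45.6% of the variance and separated the lines, with shControl libraries between -39.5 and -28.4 and shFXR libraries between 31.5 and 36.4. On the second component, with 18.5%, irradiated shFXR libraries (28.2 to 32.0) lay apart from sham shFXR libraries (-34.9 to -22.5). There the sham (-16.4 to 1.45) and irradiated (-7.14 to 18.1) shControl libraries overlapped. The third component separated these, with sham shControl libraries between -24.9 and -8.89 and irradiated ones between 3.93 and 30.6. Counts from the mitochondrial genome made up 14.4% ± 2.08 of a library in sham shControl cells, 14.8% ± 1.48 in irradiated shControl cells, 10.5% ± 0.666 in sham shFXR cells and 12.6% ± 0.418 in irradiated shFXR cells (SD, n = 3). Expression levels are given as TMM-scaled CPM (counts scaled to a common library size; mean ± SD, n = 3 per group) and changes as log2 fold changes ± standard error. Adjusted p values come from edgeR for genes and from camera for gene lists.

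The first comparison asked whether the shFXR line had lost the transcript its label names. NR1H4, which encodes the farnesoid X receptor, a nuclear receptor for bile acids, lies on chromosome 12 from 100473708 to 100564413 of hg38, on the plus strand. Its level was 23.6 ± 1.5 CPM in sham shControl cells and 4.15 ± 1.2 CPM in sham shFXR cells, a log2 fold change of -2.51 ± 0.16 (adjusted p = 2.8e-10). After radiation the levels were 24.8 ± 3.8 and 3.00 ± 0.14 CPM, a log2 fold change of -3.05 ± 0.17 (adjusted p = 2.9e-11). Raw counts were 385 to 537 in the shControl libraries and 50 to 92 in the shFXR libraries, so every shFXR library lay below every shControl library. Radiation itself gave log2 fold changes of NR1H4 of 0.07 ± 0.13 in shControl cells and -0.47 ± 0.20 in shFXR cells (adjusted p = 0.79 and 0.10). The labels write FXR only. FXR1 and FXR2, RNA-binding proteins whose symbols share these letters, changed by 0.25 ± 0.08 and -0.42 ± 0.08 between the sham lines (adjusted p = 0.014 and 5.6e-04). Their relative FMR1 had a log2 fold change of 0.05 ± 0.08 (adjusted p = 0.67). NR0B2, a classical target of the receptor, had too few counts to be tested.

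**Figure D1:**
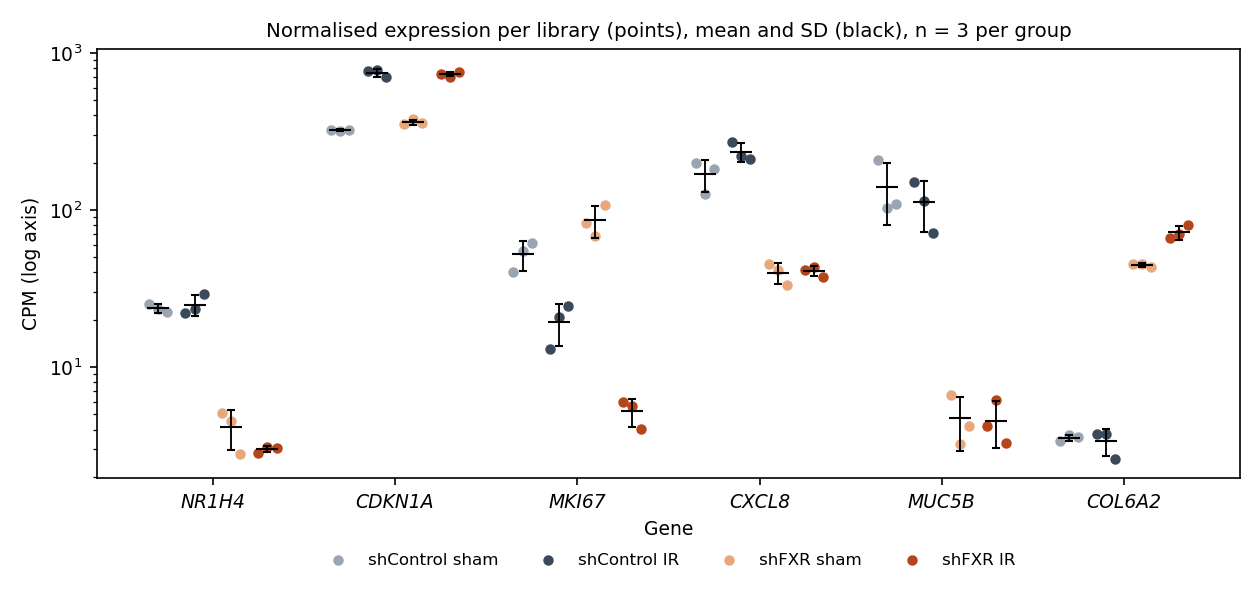
Normalised expression (CPM, log axis) of 6 named genes in each of the 12 libraries. Points are libraries, and black marks give the mean and SD of each group (n = 3). NR1H4, CXCL8 and MUC5B were lower and COL6A2 was higher in shFXR than in shControl cells, CDKN1A rose and MKI67 fell after radiation in both lines.

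In shControl cells, the comparison of irradiated with sham cells asked which transcripts still differed 3 days after radiation. CDKN1A, which encodes the cell cycle inhibitor p21, rose 2.32-fold from 323 ± 2.7 to 748 ± 43 CPM (log2 1.21 ± 0.07, adjusted p = 2.9e-09). MDM2, which encodes the ubiquitin ligase that restrains p53, rose 2.21-fold from 83.8 ± 5.2 to 185 ± 8.5 CPM (log2 1.14 ± 0.07, adjusted p = 9.5e-09). MKI67, the gene of the proliferation marker Ki-67, fell by 1.42 ± 0.19 on the log2 scale, from 52.2 ± 11 to 19.4 ± 5.8 CPM (adjusted p = 1.3e-04). TOP2A, a DNA topoisomerase of dividing cells, fell by 0.98 ± 0.17. The stress cytokine GDF15 rose by 1.10 ± 0.10. The epithelial adhesion gene CDH1 rose by 0.32 ± 0.10 and passed narrowly (adjusted p = 0.050), but with total count scaling it did not (adjusted p = 0.11).

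Of 35 measured p53 targets, 30 rose and 0 fell in shControl cells, and 31 rose when adjusted over the list alone (median log2 0.57, camera adjusted p = 2.0e-35, adjusted p = 2.1e-04 with an estimated correlation). Among 33 apoptosis regulators 7 rose, 10 when adjusted over the list alone, where 2 also fell (adjusted p = 1.5e-04, and 0.040 with an estimated correlation). They included the death receptor genes FAS (0.65 ± 0.10), TNFRSF10B (0.39 ± 0.07) and TNFRSF10A (0.50 ± 0.09), which the p53 list holds too. G2/M and mitosis genes fell in 32 of 35 cases, and in all 35 when adjusted over the list alone, with a median of -1.21. The kinesin KIF2C fell by 1.67 ± 0.18, CCNB2 by 1.26 ± 0.16 and PTTG1 by 1.03 ± 0.11. This list had an adjusted p of 8.7e-35 at the preset correlation and an adjusted p = 0.16 with an estimated correlation. Of 36 DNA replication and S phase genes 15 fell (22 adjusted over the list alone), among them CDC45 (-1.50 ± 0.26), CDT1 (-0.95 ± 0.12) and MCM7 (-0.83 ± 0.12). Of 24 homologous recombination and Fanconi genes 12 fell (16 adjusted over the list alone), among them EME1 (-1.39 ± 0.25). Their camera adjusted p values were 6.1e-11 and 3.1e-07, and the adjusted p = 0.43 with an estimated correlation for each.

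Outside these lists, the largest rises in shControl cells included ANKRD1 (1.94 ± 0.29), TRIM22 (1.60 ± 0.12), the acute-phase genes SAA1 (1.49 ± 0.14) and SAA2 (1.45 ± 0.21), KLHDC7A (1.29 ± 0.23) and the lipocalin gene LCN2 (1.19 ± 0.12). SAA1 and SAA2 are near-identical in sequence, so the split of reads between them is uncertain. The largest falls were in CA9, a carbonic anhydrase gene induced by hypoxia (-1.71 ± 0.38), and in the mitotic genes KIF18B (-1.67 ± 0.21), ESPL1 (-1.56 ± 0.23), NEK2 (-1.54 ± 0.19), AURKB (-1.51 ± 0.21) and CDC20 (-1.48 ± 0.26), besides KIF2C and CDC45. Interferon-stimulated genes rose in 6 of 27 cases (8 adjusted over the list alone), with SAMD9 at 0.71 ± 0.13 and IFIT2 at 0.75 ± 0.15 (camera adjusted p = 0.0011, adjusted p = 0.36 with an estimated correlation). Of 25 inflammatory cytokine and chemokine genes, 8 rose and 1 fell, and 8 and 2 when adjusted over the list alone (camera adjusted p = 0.0076, adjusted p = 0.49 with an estimated correlation). CCL2 rose by 0.49 ± 0.10, CXCL5 by 0.36 ± 0.07 and CXCL8 by 0.47 ± 0.13. The adjusted p of CXCL8, 0.030, became 0.074 when libraries were scaled by total counts. IL11 fell by 1.13 ± 0.26. Mesenchymal and matrix genes fell in 7 of 28 cases, 7 also adjusted over the list alone (COL4A2 -0.42 ± 0.07, LOXL2 -0.51 ± 0.10, VIM -0.46 ± 0.10; camera adjusted p = 1.6e-04, adjusted p = 0.43 with an estimated correlation).

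In all, 814 genes were higher and 797 lower after radiation in shControl cells (1611 of 16053), and 181 changed by at least 2-fold. Scaled by total counts alone, 576 were higher and 795 lower. In 24.7% of tested genes the groups did not overlap, against 10% by chance. The count was 562 without irradiated shControl library 2, 845 without irradiated shControl library 3 and 551 when only the 6 shControl libraries were fitted. It was 2659 when limma was allowed to weight each library by its spread, an alternative chosen after seeing the data. Replicates differed more within the shControl groups (chi-square per degree of freedom of pairs 6.52 to 25.4) than within the shFXR groups (2.54 to 7.22). The fit over all libraries pools this spread, which can call too many genes in shControl cells and too few in shFXR cells.

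In shFXR cells, the comparison of irradiated with sham cells asked the same question where the receptor transcript was reduced. MKI67 fell from 86.1 ± 20 to 5.23 ± 1.1 CPM (log2 -4.04 ± 0.23, adjusted p = 4.5e-10), TOP2A fell by 3.10 ± 0.18 and CDK1, the kinase that drives entry into mitosis, by 2.67 ± 0.15. CDKN1A rose 2.02-fold from 362 ± 13 to 731 ± 24 CPM (log2 1.01 ± 0.07, adjusted p = 2.3e-09), MDM2 rose by 0.88 ± 0.07, and BBC3, which encodes the cell death protein PUMA, by 0.87 ± 0.09. The largest falls were in DEPDC1 (-4.42 ± 0.24), NCAPG, a condensin subunit gene (-4.06 ± 0.35), NEK2 (-4.04 ± 0.24) and MKI67. Among the largest rises were CYGB, which encodes cytoglobin (1.53 ± 0.18), the sulfatase gene SULF2 (1.35 ± 0.08), the collagen gene COL7A1 (1.33 ± 0.13) and TRIM22 (1.31 ± 0.14).

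Of 35 p53 targets 24 rose in shFXR cells and 0 fell, 25 and 0 when adjusted over the list alone (camera adjusted p = 9.8e-18, and 0.0031 with an estimated correlation). G2/M and mitosis genes fell in 34 of 35 cases, 35 adjusted over the list alone, with a median of -2.78 (camera adjusted p = 7.0e-51, adjusted p = 0.083 with an estimated correlation). DNA replication and S phase genes fell in 34 of 36 cases, 35 adjusted over the list alone, with a median of -1.52, among them CDT1 (-1.48 ± 0.11) and MCM7 (-1.56 ± 0.12). Homologous recombination and Fanconi genes fell in 21 of 24 cases, the same number adjusted over the list alone, among them BRCA1 (-1.92 ± 0.16), BRIP1 (-2.02 ± 0.19) and FANCI (-1.76 ± 0.13). The camera adjusted p values of these lists were 8.5e-38 and 7.7e-22, and the adjusted p = 0.091 with an estimated correlation for each.

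Genes that rose in irradiated shFXR cells included 13 of 28 mesenchymal and matrix genes, while 1 fell, 14 and 2 when adjusted over the list alone (camera adjusted p = 7.5e-05, adjusted p = 0.32 with an estimated correlation). The collagen VI chain gene COL6A2 rose by 0.70 ± 0.09 and COL6A1 by 0.65 ± 0.08. VIM rose by 0.39 ± 0.10, while the collagen-crosslinking enzyme gene LOX fell by 0.54 ± 0.13. Fibroblast markers moved with them: 5 of 8 rose, 6 adjusted over the list alone, with ACTA2 at 0.84 ± 0.09, COL1A1 at 0.94 ± 0.21 and FAP at 0.77 ± 0.17 (camera adjusted p = 8.1e-04, adjusted p = 0.18 with an estimated correlation). Of 21 secreted factors of senescent cells 9 rose and 1 fell, 10 and 2 when adjusted over the list alone, with SERPINE2 at 1.11 ± 0.10, IGFBP7 at 1.04 ± 0.11 and TIMP2 at 0.53 ± 0.07 (camera adjusted p = 7.5e-05, adjusted p = 0.18 with an estimated correlation). Lysosome and autophagy genes rose in 19 of 32 cases, 24 adjusted over the list alone, with the lysosomal glucosidase gene GAA at 0.87 ± 0.08, GRN at 0.61 ± 0.08 and TPP1 at 0.57 ± 0.08 (camera adjusted p = 2.6e-11, adjusted p = 0.083 with an estimated correlation).

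Radiation changed 3379 genes in shFXR cells, 1744 higher and 1635 lower, of which 530 changed by at least 2-fold. Scaled by total counts alone, 1335 were higher and 1863 lower, and DESeq2 gave 1571 and 1803. The groups did not overlap in 43.7% of tested genes, against 10% by chance. This count fell to 2106 without irradiated library 3, 2127 without sham library 3, 2219 without sham library 1 and 2226 without irradiated library 1 of the shFXR line. It was 5063 when only the shFXR libraries were fitted, without the larger spread of the shControl libraries. With limma's library weights, chosen after seeing the data, it was 6298.

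**Figure D2:**
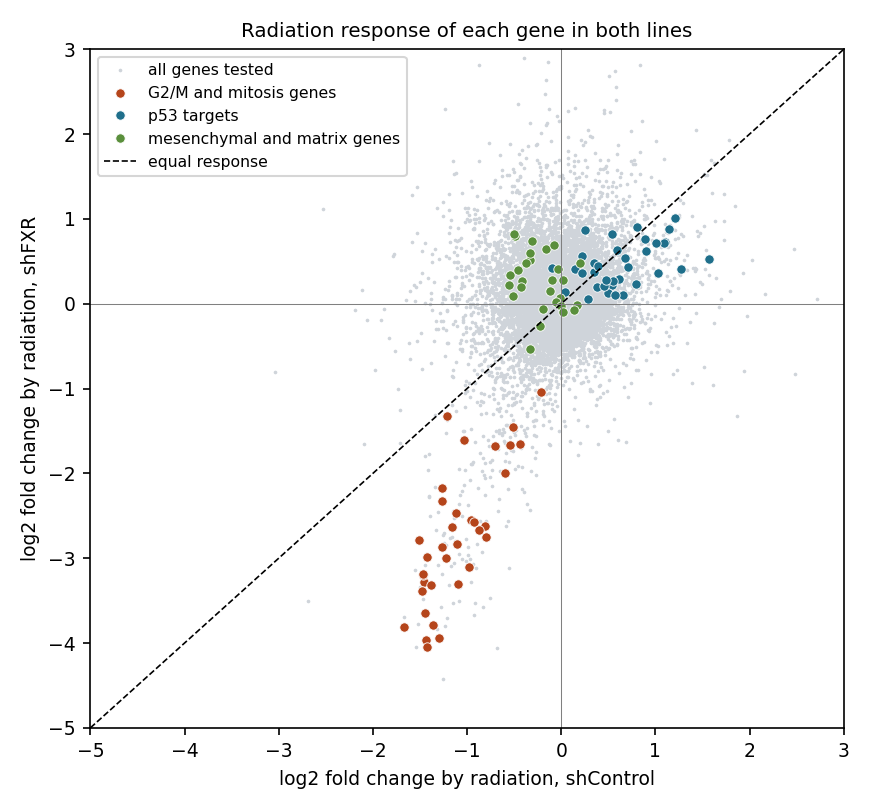
Log2 fold change after radiation of each tested gene in shControl cells (horizontal axis) and shFXR cells (vertical axis), with the members of 3 gene lists in colour, the dashed line marking equal responses, and 1 gene outside the axes. The G2/M and mitosis genes have a median of -1.21 in shControl cells and -2.78 in shFXR cells.

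The difference between these responses asks how the response to radiation differed between the lines, and was tested as the response in shFXR cells minus that in shControl cells. Differences between the lines other than the knockdown enter it too. MKI67 differed by -2.62 ± 0.30 on the log2 scale (adjusted p = 7.2e-05), TOP2A by -2.12 ± 0.24 and CDK1 by -1.80 ± 0.20, so that these proliferation genes fell further in shFXR cells. VIM, the gene of the intermediate filament vimentin, differed by 0.85 ± 0.14 (adjusted p = 0.0010), falling in shControl and rising in shFXR cells. FMR1 differed by -0.34 ± 0.11 (adjusted p = 0.041), a call lost with total count scaling and with a replicate block (adjusted p = 0.063 and 0.058). The differences of CDKN1A (-0.20 ± 0.10, adjusted p = 0.18), MDM2 (-0.26 ± 0.10, adjusted p = 0.086) and GDF15 (-0.37 ± 0.14, adjusted p = 0.072) did not pass in edgeR. DESeq2 gave adjusted p values of 0.045, 0.035 and 0.045, and GDF15 also passed with total count scaling (adjusted p = 0.042).

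The response was lower in shFXR cells for 33 of 35 G2/M and mitosis genes (33 adjusted over the list alone, median -1.71), 28 of 36 DNA replication and S phase genes (32 adjusted over the list alone, median -0.97) and 13 of 24 homologous recombination and Fanconi genes (19 adjusted over the list alone, median -0.94). Camera adjusted p values were 4.5e-27, 5.4e-20 and 2.8e-09, and with an estimated correlation the adjusted p = 0.24, 0.24 and 0.26. The DNA repair gene BRCA1 differed by -1.50 ± 0.23. The largest negative differences were in NCAPG (-3.38 ± 0.46), DEPDC1 (-3.16 ± 0.33), EXO1 (-2.75 ± 0.48), ANKRD1 (-2.73 ± 0.38), ESCO2 (-2.71 ± 0.39), DLGAP5 (-2.65 ± 0.33), MKI67 and MCM10 (-2.61 ± 0.50). ANKRD1, unlike the others, rose in shControl cells and had a log2 change of -0.79 ± 0.25 in shFXR cells, where its call was lost in DESeq2 (adjusted p = 0.11).

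Higher responses in shFXR cells were found for 13 of 28 mesenchymal and matrix genes, 14 adjusted over the list alone (median 0.52), for 8 of 21 secreted factors of senescent cells, 10 adjusted over the list alone (median 0.47), and for 3 of 8 fibroblast markers, 7 adjusted over the list alone (median 0.64). Camera adjusted p values were 1.3e-07, 2.1e-06 and 4.8e-04, and the adjusted p = 0.24 with an estimated correlation for each. SERPINE2 differed by 1.08 ± 0.14 and FAP by 1.26 ± 0.24. SERPINA5 (1.92 ± 0.47), SPOCK1, a matrix proteoglycan gene (1.81 ± 0.22), SMOC1 (1.64 ± 0.28), CDK18 (1.52 ± 0.37), LMNTD2 (1.49 ± 0.26), ASIC3 (1.45 ± 0.24), PAQR6 (1.43 ± 0.21) and SEC31B (1.42 ± 0.23) had the largest positive differences.

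The responses differed for 2405 genes, 1173 higher and 1232 lower in shFXR cells, with 477 at a 2-fold difference or more. Without a single library the count was 1162 (irradiated shControl 3), 1243 (irradiated shFXR 3), 1445 (sham shFXR 3), 1571 (irradiated shControl 2) or 1595 (sham shFXR 1). With limma's library weights, chosen after seeing the data, it was 4300. Across all tested genes the responses had a Pearson correlation of 0.22 and a Spearman correlation of 0.06, without a p value since genes are not independent replicates. Most of these genes had no called change, and noise in their fold changes pulls both correlations towards 0. The Pearson value was 0.35 among genes with a mean of 5 CPM or more, and 0.073 without irradiated shControl library 1. Of 582 genes called in both lines, 81.3% changed in the same direction. There were 181 that rose in both, where 88.4 would do so if calls were independent, and 292 that fell in both, where 81.2 would. The remaining 109 moved in opposite directions. Over the 2700 genes with a radiation effect averaged over the lines, the response in the direction of that effect was larger in shFXR cells by a median of 0.16 on the log2 scale, and 65.9% of these genes had the larger response in shFXR cells. This median was 0.086 without sham shControl library 3 and 0.11 without irradiated shControl library 1. Camera on the difference gave p = 3.2e-12 for the falling and p = 3.0e-04 for the rising genes of this set, and p = 0.079 and p = 0.056 with an estimated correlation.

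Between the sham lines, the comparison asked what differed with the knockdown before any radiation. The chemokine gene CXCL8 fell from 169 ± 39 to 40.0 ± 6 CPM (log2 -2.08 ± 0.14, adjusted p = 7.7e-10). CCL2 fell from 41.1 ± 6.4 to 2.76 ± 0.22 CPM (log2 -3.89 ± 0.14, adjusted p = 6.0e-14) and the airway mucin gene MUC5B from 140 ± 60 to 4.71 ± 1.8 CPM (log2 -4.90 ± 0.32, adjusted p = 4.2e-10). COL6A2, a collagen VI chain gene, rose 12.6-fold from 3.54 ± 0.16 to 44.6 ± 1.1 CPM (log2 3.65 ± 0.12, adjusted p = 1.7e-14). The cell adhesion gene CDH1 (E-cadherin) fell by 1.18 ± 0.11, IL6 fell by 2.41 ± 0.36 from 4.33 ± 0.79 CPM, and CD274, the gene of the checkpoint ligand PD-L1, was below 1 CPM in every group. MDM2 was lower by a log2 change of -0.25 ± 0.07 (adjusted p = 0.010, and 0.089 with total count scaling) and TOP2A higher by 0.50 ± 0.16 (adjusted p = 0.019, and 0.080 in DESeq2). CDKN1A, at 0.16 ± 0.07 (adjusted p = 0.068), passed with RLE scaling, total count scaling and DESeq2 (adjusted p = 0.049, 0.011 and 0.0073).

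Of 25 inflammatory cytokine and chemokine genes, 17 were lower and 5 higher in sham shFXR cells, and the same numbers when adjusted over the list alone (median -1.30, camera adjusted p = 2.4e-06, adjusted p = 0.11 with an estimated correlation). CXCL1 fell by 2.04 ± 0.10, while BIRC3, an inhibitor of apoptosis gene, rose by 0.92 ± 0.13. Interferon-stimulated genes were lower in 21 of 27 cases and higher in 0, also adjusted over the list alone, with IRF1 at -1.25 ± 0.10, IFIT1 at -1.38 ± 0.12 and OAS1 at -1.24 ± 0.12 (median -0.88, adjusted p = 3.4e-07, and 0.045 with an estimated correlation). Secreted factors of senescent cells were lower in 14 of 21 cases and higher in 5, also adjusted over the list alone, with the protease gene PLAU at -1.46 ± 0.08 and ANGPTL4 at 1.16 ± 0.12 (camera adjusted p = 0.0020, adjusted p = 0.24 with an estimated correlation).

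Among 16 measured FXR target and bile acid genes, 8 were lower and 1 higher, with the same numbers adjusted over the list alone (median -0.35, mean -0.95, camera adjusted p = 0.0012, adjusted p = 0.083 with an estimated correlation). The fibrinogen genes FGG, FGA and FGB fell by 2.67 ± 0.14, 2.31 ± 0.14 and 1.62 ± 0.12, and SLC51B, which encodes a bile acid transporter subunit, fell by 1.48 ± 0.21, whereas FABP6, a bile acid binding protein gene, rose by 0.91 ± 0.22. Cholesterol synthesis genes were lower in 20 of 25 cases and higher in 1, also adjusted over the list alone, with MSMO1 at -1.65 ± 0.09 and IDI1 at -1.41 ± 0.07 (median -0.68, adjusted p = 4.1e-14, and 0.040 with an estimated correlation). Fatty acid synthesis genes were lower in 15 of 24 cases and higher in 3, 17 and 3 when adjusted over the list alone (adjusted p = 3.5e-07, and 0.040 with an estimated correlation). SCD, the stearoyl-CoA desaturase gene, fell by 0.96 ± 0.07 and ACLY by 0.81 ± 0.07, and DGAT2 rose by 0.81 ± 0.17. Of 30 ATF4 and unfolded protein response genes 13 were lower and 2 higher, 13 and 3 adjusted over the list alone, with TRIB3 at -1.61 ± 0.09 and XBP1 at -0.96 ± 0.07 (adjusted p = 0.0012, and 0.040 with an estimated correlation).

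Epithelial junction and keratin genes were lower in 13 of 26 cases and higher in 4, 15 and 4 when adjusted over the list alone (median -0.63, adjusted p = 0.0012, and 0.040 with an estimated correlation). CLDN2, a tight junction gene, fell by 4.43 ± 0.11, KRT19 by 1.32 ± 0.11 and JUP by 0.90 ± 0.08, while CLDN1 rose by 0.56 ± 0.07. Lung alveolar and airway genes were lower in 8 of 13 cases and higher in 2, 10 and 2 adjusted over the list alone, with MUC5AC at -3.28 ± 0.31 beside MUC5B (the split of reads between these similar genes is uncertain) and CAV1 at 0.70 ± 0.11 (camera adjusted p = 0.0032, adjusted p = 0.080 with an estimated correlation). Mesenchymal and matrix genes were higher in 20 of 28 cases and lower in 1, 22 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 7.2e-09, adjusted p = 0.090 with an estimated correlation). COL6A1 rose by 2.07 ± 0.09 and TAGLN by 1.86 ± 0.14 and LAMB3 fell by 0.49 ± 0.09. VIM, at 0.25 ± 0.10, did not pass (adjusted p = 0.052) except under DESeq2, RLE scaling, total count scaling and a replicate block (adjusted p = 0.029, 0.041, 0.0090 and 0.046).

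DNA replication and S phase genes were higher in 25 of 36 cases in sham shFXR cells, and homologous recombination and Fanconi genes in 18 of 24, with 25 and 19 adjusted over the list alone and none lower. PRIM1 rose by 1.17 ± 0.17, MCM2 by 0.97 ± 0.14 and FANCA by 0.86 ± 0.14. Of 35 G2/M and mitosis genes 14 were higher, 15 adjusted over the list alone, with MKI67 at 0.72 ± 0.18, FOXM1 at 0.70 ± 0.15 and KIF11 at 0.63 ± 0.13. Camera adjusted p values of these lists were 5.5e-09, 3.4e-07 and 6.2e-05, and with an estimated correlation the adjusted p = 0.27, 0.21 and 0.42. Of 35 p53 targets 18 were higher and 7 lower, 19 and 9 adjusted over the list alone, with AEN at 0.85 ± 0.07 and GDF15 at -0.74 ± 0.10 (camera adjusted p = 0.011, adjusted p = 0.13 with an estimated correlation). Other large rises were in SCG2 (2.71 ± 0.18), ANKRD1 (2.39 ± 0.28), SHROOM2 (2.31 ± 0.23), the hyaluronan synthase gene HAS2 (2.30 ± 0.13), CACNG7 (2.27 ± 0.19) and HMGA2 (2.11 ± 0.10). Other large falls were in S100A9 (from 49.1 ± 17 to 1.53 ± 0.1 CPM, adjusted p = 1.8e-10), SPDEF, a transcription factor gene of mucous cells (-4.91 ± 0.24), FCGBP (-4.13 ± 0.30), CPLX2 (-4.00 ± 0.15) and RARRES1 (-3.88 ± 0.18).

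Markers of other cell types moved between the sham lines too. Of 7 measured hepatocyte markers 5 were lower in shFXR cells, also adjusted over the list alone, which includes FGA and FGB and the haptoglobin gene HP (-5.63 ± 0.56, from 3.02 ± 0.78 CPM; camera adjusted p = 9.5e-05, adjusted p = 0.080 with an estimated correlation). The monocyte marker CD14 fell from 45.8 ± 12 to 8.66 ± 0.97 CPM, and the fibroblast marker DCN rose from 13.2 ± 2.1 to 24.8 ± 3.6 CPM. Of 5 endothelial markers 3 were lower and 0 higher, 4 and 0 adjusted over the list alone, with EGFL7 at -0.84 ± 0.10 (median -1.13, camera adjusted p = 0.064). The leukocyte and fibroblast lists went both ways: of 4 measured leukocyte markers 1 was higher (ITGAM, 0.89 ± 0.28) and 1 lower, and of 8 fibroblast markers 3 were higher and 3 lower (camera adjusted p = 0.59, adjusted p = 0.68 with an estimated correlation), among them FAP (-0.64 ± 0.17). The sham lines differed in 6003 of 16053 genes, 2885 higher and 3118 lower in shFXR cells, with 1185 at 2-fold or more. The groups did not overlap in 46.9% of tested genes, against 10% by chance. Scaled by total counts alone, 3820 were higher and 2465 lower. The labels do not tell shFXR lines apart or state their number, so every difference between the lines, from the knockdown or otherwise, enters this comparison.

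After radiation, the same comparison of the lines asked which of these differences were present in irradiated cells. CXCL8 was lower in shFXR cells, at 40.8 ± 3 against 234 ± 32 CPM (log2 -2.52 ± 0.14, adjusted p = 4.5e-11). SLC51B was lower by a log2 change of -2.03 ± 0.21, and COL6A2 was 21.4-fold higher, at 72.2 ± 7.4 against 3.37 ± 0.66 CPM (log2 4.42 ± 0.12, adjusted p = 5.4e-16). MKI67 was lower, at 5.23 ± 1.1 against 19.4 ± 5.8 CPM (log2 -1.90 ± 0.24, adjusted p = 2.5e-06), the opposite of the sham comparison. VIM was 2.15-fold higher (log2 1.10 ± 0.10), and CDKN1A had a log2 fold change of -0.03 ± 0.07 (adjusted p = 0.73).

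G2/M and mitosis genes were lower in 34 of 35 cases in irradiated shFXR cells, also adjusted over the list alone (median -1.33, camera adjusted p = 2.0e-10, adjusted p = 0.30 with an estimated correlation), among them CDK1 (-1.63 ± 0.15) and TPX2 (-1.53 ± 0.15). DNA replication and S phase genes were lower in 17 of 36 cases and higher in 1, also adjusted over the list alone, with PCNA at -1.18 ± 0.11 and CDT1 at 0.37 ± 0.12 (camera adjusted p = 0.0020, adjusted p = 0.57 with an estimated correlation). Mesenchymal and matrix genes were higher in 23 of 28 cases, 24 adjusted over the list alone, with COL6A1 at 2.88 ± 0.09 and COL5A1 at 2.39 ± 0.12 (median 0.92, camera adjusted p = 3.2e-16, adjusted p = 0.060 with an estimated correlation). Of 8 fibroblast markers 7 were higher, also adjusted over the list alone, with DCN at 1.39 ± 0.13, ACTA2 at 0.99 ± 0.09 and THY1 at 0.62 ± 0.13 (camera adjusted p = 4.2e-04, adjusted p = 0.14 with an estimated correlation).

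Inflammatory cytokine and chemokine genes were lower in 16 of 25 cases and higher in 6, interferon-stimulated genes lower in 20 of 27 and higher in 1, and cholesterol synthesis genes lower in 22 of 25 and higher in 2. When adjusted over the list alone these numbers were 16 and 6, 20 and 1, and 23 and 2. Camera adjusted p values were 2.8e-04, 3.1e-07 and 1.1e-12, and with an estimated correlation the adjusted p = 0.25, 0.060 and 0.060. CXCL5 was lower by a log2 change of -1.52 ± 0.07, IRF1 by -1.28 ± 0.10 and IDI1 by -1.82 ± 0.08, while NFKB2 was higher (0.95 ± 0.09). FXR target and bile acid genes were lower in 8 of 16 cases and higher in 3, 8 and 4 adjusted over the list alone, with FGG at -2.70 ± 0.15 and FGFR4 at 0.84 ± 0.11 (camera adjusted p = 0.022, adjusted p = 0.23 with an estimated correlation). Hepatocyte markers, which share FGA and FGB with that list, were lower in 6 of 7 cases, also adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.073 with an estimated correlation). The largest rises, besides the collagen genes, were in CACNG7 (3.60 ± 0.21), the basement membrane gene NID1 (3.19 ± 0.14), SPOCK1 (2.91 ± 0.16), SCG2 (2.63 ± 0.19), HAS2 (2.44 ± 0.13) and KCNH3 (2.43 ± 0.20). The largest falls were in S100A9 (-5.16 ± 0.33), CPLX2 (-5.15 ± 0.17), LCN2 (-5.06 ± 0.17), CLDN2 (-5.06 ± 0.12), MUC5B (-4.63 ± 0.32), CCL2 (-4.06 ± 0.13), TRIM31 (-3.68 ± 0.21) and SAA2 (-3.66 ± 0.25).

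The irradiated lines differed in 6557 genes, 3138 higher and 3419 lower in shFXR cells, with 1344 at 2-fold or more. With total count scaling, 3605 were higher and 2799 lower. The groups did not overlap in 52.9% of tested genes, against 10% by chance. Across genes the knockdown effects without and with radiation had a Pearson correlation of 0.65 and a Spearman correlation of 0.49. Of 3499 genes called in both, 93.5% had the same direction: 1417 were higher in both, where 564 would be if calls were independent, 1854 were lower in both, where 664 would be, and 228 went opposite ways.

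**Figure D3:**
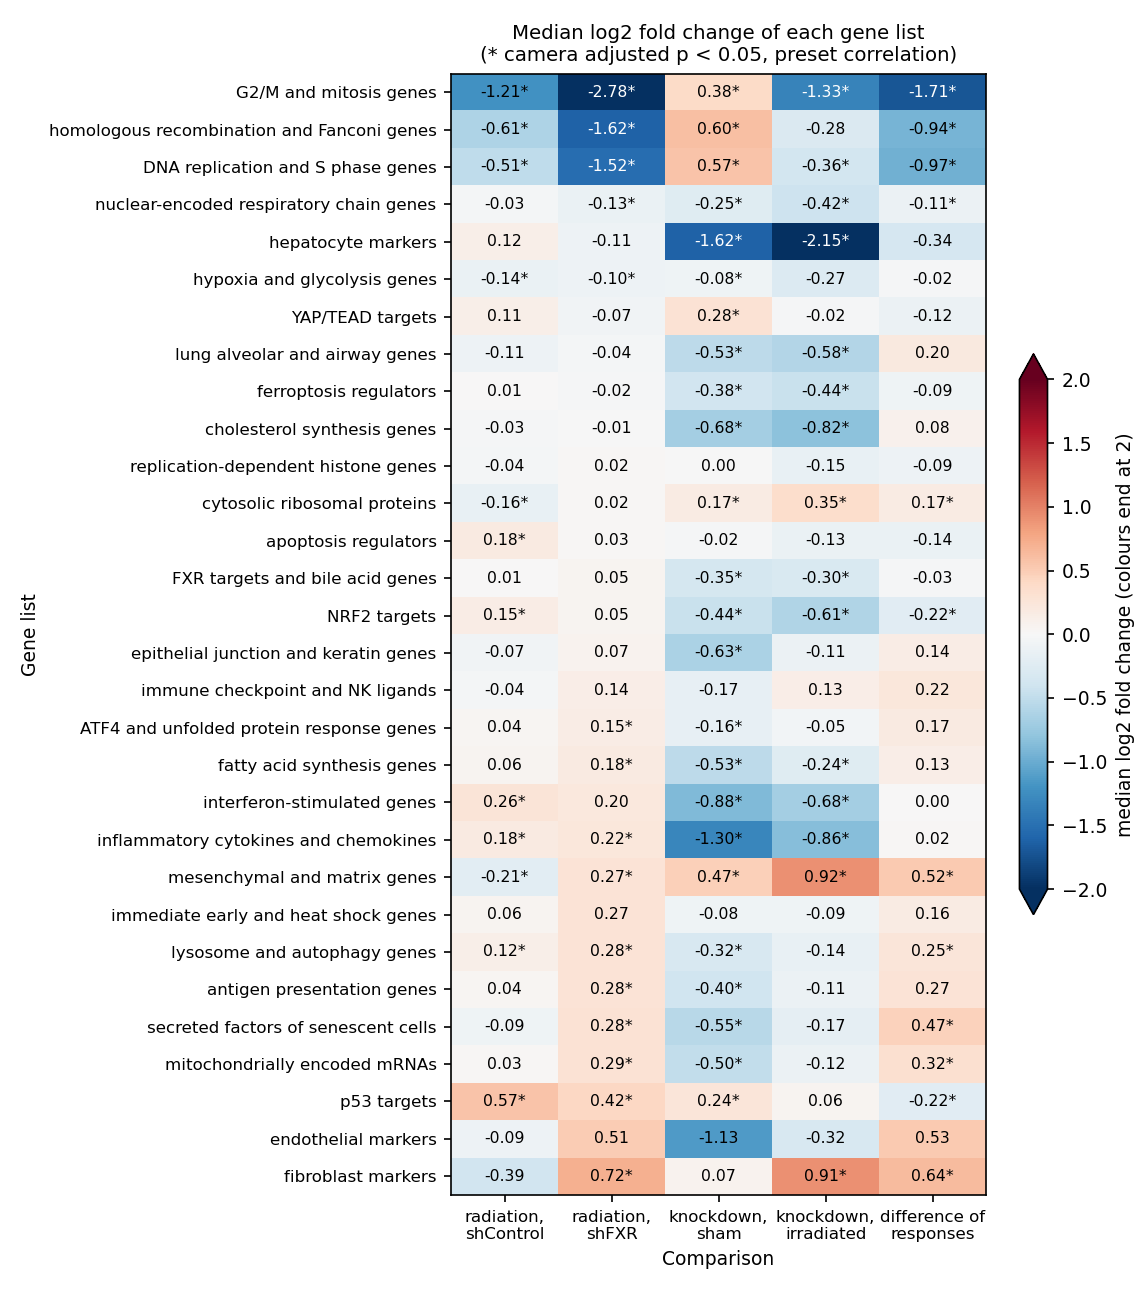
Median log2 fold change of each gene list with at least 5 measured members (vertical axis) in each comparison (horizontal axis), with colours from -2 (blue) to 2 (red) and an asterisk where camera with its preset correlation passed. The G2/M and mitosis list has the lowest median in the difference of responses, at -1.71.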

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

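The tests on single libraries, starting level, fibroblast transcripts and transcripts of other cells were chosen only after the result was seen.

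The response to radiation differed between the lines for 2405 genes. The lists with a called difference had median log2 differences of -1.71 (G2/M and mitosis), -0.97 (DNA replication and S phase), -0.94 (homologous recombination and Fanconi), -0.22 (p53 targets), -0.22 (NRF2 targets), -0.11 (respiratory chain), 0.17 (ribosomal proteins), 0.25 (lysosome and autophagy), 0.32 (mitochondrially encoded mRNAs), 0.47 (secreted factors of senescent cells), 0.52 (mesenchymal and matrix) and 0.64 (fibroblast markers), and none of these calls was kept with an estimated correlation. Single genes with lower responses in shFXR cells were NCAPG (-3.38), DEPDC1 (-3.16), EXO1 (-2.75), ANKRD1 (-2.73), ESCO2 (-2.71), DLGAP5 (-2.65), MKI67 (-2.62), MCM10 (-2.61), TOP2A (-2.12), CDK1 (-1.80), BRCA1 (-1.50), GCLM (-0.71), NDUFS1 (-0.59) and FMR1 (-0.34). Higher responses were found for SERPINA5 (1.92), SPOCK1 (1.81), SMOC1 (1.64), CDK18 (1.52), LMNTD2 (1.49), ASIC3 (1.45), PAQR6 (1.43), SEC31B (1.42), FAP (1.26), SERPINE2 (1.08), VIM (0.85), GAA (0.72), MT-ND6 (0.67), BBC3 (0.62) and RPL28 (0.47). The call of MT-ND6 was lost in DESeq2 (adjusted p = 0.057), and that of FMR1 with total count scaling and a replicate block (adjusted p = 0.063 and 0.058).

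G2/M and mitosis genes fell further after radiation in shFXR cells, with a median difference of -1.71. A single deviating library is argued against by the fits without 1 library, of which the one nearest to 0 still gave -1.52. Of the 35 genes 14 were higher in sham shFXR cells (camera adjusted p = 0.42 with an estimated correlation), and a higher starting level alone is argued against by where they ended, with a median of -1.33 between the irradiated lines and list scores of -2.43 to -2.23 in shFXR against -1.43 to -0.77 in shControl cells. A difference between the stable lines other than the knockdown cannot be told apart from it, since the labels tell only 1 shFXR line apart and do not state the number of lines.

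Of 28 mesenchymal and matrix genes 13 had a higher response to radiation in shFXR cells and 0 a lower one, with a median difference of 0.52 (camera adjusted p = 0.24 with an estimated correlation). The fits without 1 library gave 0.457 to 0.589, and removal of a trend with gene length left 0.477 (quartiles 0.0890 and 0.845), against either as the whole cause. Fibroblasts in the irradiated shFXR cultures are argued against by COL1A2 and COL3A1, whose summed level went from 0.954 to 0.739 CPM, a change of -0.215. COL6A1 and COL6A2 together rose by 68.6 CPM (all CPM by total counts, without TMM). The fibroblast marker list went the other way, with COL1A1 among its rising members. Its mean score was 0.143 in sham and 0.691 in irradiated shFXR cells. Fibroblasts are thus not excluded, and a property of this shFXR line stays open.

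Chemokine, airway mucin and fibrinogen transcripts were lower in sham shFXR cells. The inflammatory, lung alveolar and airway and hepatocyte marker lists, pooled after the result was seen and without a set test of their own, held 45 measured genes, of which 30 were lower, 7 higher and the median was -0.93. After removal of a trend with gene length the median was -0.846. Hepatocytes as the other cells in the shControl cultures would bring their abundant transcripts, yet ALB, APOA1, APOA2 and TTR together were at 0.520 CPM beside 1244 CPM of FGA and FGB (CPM by total counts, without TMM). These values speak to hepatocytes as a source of the fibrinogen transcripts only. Cells of other types as a source of the chemokine and mucin transcripts were not tested. A difference between the stable lines other than the knockdown cannot be told apart from it, since the labels tell only 1 shFXR line apart and do not state the number of lines.

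For the difference of responses, 82 splits balanced over line and radiation were run. Only the real one (1 of 82) gave as many genes, with 2405 against at most 1 in the others. This share, the smallest that 82 splits can give, argues against a chance assignment of libraries but does not exclude it. In the other splits the real difference adds to the residual spread and holds their counts down, so the gap in counts does not measure the evidence. For the other counts the 10 splits are too few for a share under 0.05, with 1 split, the real one, as large in each. The real values and the highest others were 1611 and 6 for radiation in shControl cells, 3379 and 0 for radiation in shFXR cells, 6003 and 0 for the knockdown under sham irradiation and 6557 and 0 for the knockdown after radiation.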

How the results depend on the processing

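Leaving out mitochondrial genes and limma with voom sample weights were chosen only after the result was seen.

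No clear pairing of libraries by replicate number was seen. The 18 pairs with the same number had r from -0.14 to 0.23, and pairs with other numbers from -0.18 to 0.16. A weak pairing is not excluded. With a replicate block the 5 counts were 1553, 3236, 5889, 6463 and 2358. Radiation in shControl cells gave 1611 genes, 551 with only the groups compared, 2659 with voom sample weights and 562 to 1932 without 1 library. Radiation in shFXR cells gave 3379 genes, 5063 with only the groups compared, 6298 with voom sample weights and 2106 to 2553 without 1 library. The difference of responses gave 2405 genes, 4300 with voom sample weights and 1162 to 3254 without 1 library. Voom gave sham shControl library 2 a weight of 0.244 and irradiated shControl library 3 a weight of 0.496, against up to 3.13. The cause was not tested. The counts for the knockdown stayed within 1.5 times under the alternatives run, at 4973 to 6730 and 5394 to 8812, although with total counts only 60.8% and 56.3% of the called genes were higher, where TMM gave 48.1% and 47.9%. For radiation these shares were 42.0% in shControl and 41.7% in shFXR cells, where TMM gave 50.5% and 51.6%.

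The agreement of radiation responses was 0.22, 0.35 with the strict filter and 0.073 to 0.30 without 1 library. The size of the response was 0.16, and 0.086 to 0.23 without 1 library. The agreement of knockdown effects was 0.65, 0.70 with the strict filter and 0.56 to 0.67 without 1 library. NR1H4 stayed between -2.66 and -2.28 under sham irradiation (adjusted p at most 1.7e-07) and between -3.12 and -2.91 after radiation (at most 2.0e-09).

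Of 150 gene list tests 78 passed with the preset correlation and 8 with an estimated correlation. With fry 77 passed, but 18 calls of the preset test were lost and 17 others were gained. At 17.1 to 19.0 M counts 34.4% of simulated 1.5-fold differences of responses were found. The simulations changed far fewer genes than were called in these data, so this share does not carry over to them. The called differences of responses had a median absolute log2 size of 0.57.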

Other observations

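The test of the p53 target list against the deeper fall of cell cycle genes was chosen only after the result was seen.

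NRF2 targets, genes of the antioxidant response, rose in 9 of 33 cases and fell in 1 after radiation in shControl cells (ALDH3A1 0.93 ± 0.11, GCLM 0.48 ± 0.08; camera adjusted p = 5.9e-06, 0.43 with an estimated correlation). In sham shFXR cells 24 were lower and 4 higher (GPX2 -2.56 ± 0.15, EPHX1 -1.69 ± 0.11; adjusted p = 3.5e-07, 0.12 with an estimated correlation). Lysosome and autophagy genes were lower in 24 of 32 cases in sham shFXR cells, with the protease gene CTSD at -1.88 ± 0.12 (adjusted p = 1.3e-08, 0.070 with an estimated correlation). Ferroptosis regulators were lower in 15 of 28 cases and higher in 3 (SAT1 -1.68 ± 0.10; adjusted p = 2.0e-04, 0.059 with an estimated correlation). Antigen presentation genes were lower in 12 of 21 (PSMB8 -0.63 ± 0.10; adjusted p = 9.2e-04, 0.090 with an estimated correlation), and YAP/TEAD targets were higher in 13 of 26 and lower in 3 (AXL 0.66 ± 0.07; adjusted p = 3.1e-04, 0.12 with an estimated correlation). Hypoxia and glycolysis genes fell after radiation in 5 of 34 cases and rose in 1 in shControl cells (NDRG1 -0.81 ± 0.17; adjusted p = 6.6e-04, 0.43 with an estimated correlation). In shFXR cells 11 fell and 2 rose (LDHA -0.62 ± 0.09; adjusted p = 0.020, 0.42 with an estimated correlation), and the difference of responses had an adjusted p of 0.99.

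Of 13 mitochondrially encoded mRNAs 12 were lower in sham shFXR cells (MT-CO1 -0.65 ± 0.11; adjusted p = 3.5e-05, 0.30 with an estimated correlation), against 4 in irradiated shFXR cells (adjusted p = 0.17). Sham shControl library 2 stood apart in this list, with a score of 0.346 where the other sham shControl libraries had -0.193 and -0.153 and the sham shFXR libraries -0.559 to -0.358. Nuclear-encoded respiratory chain genes were lower in 25 of 35 cases in irradiated shFXR cells (ATP5F1B -0.93 ± 0.08; adjusted p = 4.3e-08, 0.34 with an estimated correlation). In the same cells cytosolic ribosomal protein genes were higher in 29 of 36 and lower in 1 (RPL13 0.58 ± 0.09, RPL19 -0.63 ± 0.09; adjusted p = 1.5e-09, 0.39 with an estimated correlation). Replication-dependent histone genes, immune checkpoint and NK ligands, immediate early and heat shock genes and endothelial markers did not pass in any comparison, with camera adjusted p values between the sham lines of 0.86, 0.86, 0.69 and 0.064. Poly-T selection largely misses histone mRNAs without a poly-A tail. The histone list therefore cannot show whether those transcripts changed. Of the leukocyte markers 4 and of the erythroid markers 0 were measured, too few to test. In 15 of 150 list tests the median, mean and camera direction differed in sign, and 0 of these were called.

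A larger p53 response in shFXR cells could explain the deeper fall of cell cycle genes there, since p53 targets include the cell cycle inhibitor gene CDKN1A. A larger rise of the p53 target list is argued against, as its median difference between the responses was -0.22, with 3 of 35 members higher and 6 lower in shFXR cells (camera adjusted p = 0.013, 0.24 with an estimated correlation). In sham shFXR cells 18 members were higher and 7 lower, and after radiation the mean scores were 0.648 in irradiated shFXR and 0.634 in irradiated shControl cells. Between the irradiated lines 11 members were higher and 7 lower (median 0.06, camera adjusted p = 0.50). Other routes to the deeper fall were not tested and stay open, as a hypothesis for other lines and hairpins.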
